A study of Mus musculus with 20 samples.

How the data were processed

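Per the labels, RNA was extracted with TRIzol from 30 µm cryosections of tumors or from organoids, and polyadenylated RNA was made into TruSeq libraries and sequenced. The authors list CASAVA, FastQC, STAR, HTSeq and DESeq2, without versions, and the mouse genome mm10. The deposited values used here are raw counts of reads per gene from htseq-count, 1 table per library with 45318 versioned Ensembl gene IDs; reads that matched no gene, several genes or several places are listed apart from the genes. The annotation release, the strand setting and the counting mode are not stated. Gene names, types and positions were taken from GENCODE M21, which matched 44671 of the IDs without their version (21578 protein coding, 7898 long noncoding). Total gene counts ranged from 17478357 (PyMT tumor section replicate 2) to 48341438 (Neu-NDL replicate 1). Between 4.77 and 10.75% of reads fell on no gene, 4.04 to 6.54% were ambiguous, and 1.23 to 6.04% of gene counts were mitochondrial.

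Libraries were grouped by the labels into WT organoids (n = 3), PyMT tumor sections (n = 3), PyMT organoids at day 0 (n = 3), at day 6 (n = 3) and undated (n = 2), Neu-NDL organoids (n = 3) and Neu-NT tumor sections (n = 3). A single edgeR 4.0.16 quasi-likelihood model over all 20 libraries (R 4.3.3; TMM scaling, filterByExpr, robust dispersion, 1 mean per group, 13 residual degrees of freedom) tested 18698 genes, 1967 of them long noncoding, with a common dispersion of 0.193. The 6 day PyMT comparisons averaged the day 6 and undated groups with equal weight. Calls used a Benjamini-Hochberg adjusted p under 0.05 within each comparison. SE is the log2 fold change divided by the square root of its F statistic. CPM are counts scaled to TMM-adjusted library sizes with the cpm function of edgeR, and log2 CPM used a prior count of 2. For genes with 0 counts in a group, fold differences were computed against a floor of 3 counts over the group; with 1 to 3 counts, the ratio is given with its exact 95% interval for counting error.

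The comparisons, 27 gene lists (517 entries, 507 found in the tables) and the rule for named genes were fixed before the data were examined. List members were counted with p-values adjusted over all genes and over the list alone, and lists were tested against other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The lists whose results are printed are those with a call or a bearing on a comparison. The rule named, in each comparison with WT organoids and in the others that had calls, the 8 genes with the largest rise and the 8 with the largest fall among those with an adjusted p under 0.05, at least 10 CPM in the higher group and no overlap between the libraries of the 2 sides (an arrangement that chance gives for 10% of genes with 3 against 3), leaving out predicted names; 4 long noncoding or predicted genes higher than WT organoids per comparison; up to 10 long noncoding genes higher in all 4; and Erbb2. The text gives a selection of these, and list members as examples of their lists.

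Whether replicate numbers pair the samples was checked by correlating, over genes, the deviations from the group means of libraries with the same number. Only day 6 and day 0 PyMT organoids passed (r 0.287 to 0.428 over genes, all 3 pairs above 0.1, where genes are not independent replicates). That comparison was also fitted with the replicate number as a block. The labels do not state pairs. Deviations within a group depend on each other, so the 3 values of r are not separate evidence. On simulated data for 3 Neu-NDL against 3 WT libraries, edgeR recovered 11% of 100 genes changed 2-fold and 47% of 100 changed 4-fold. Of its calls 7.94% were unchanged genes. DESeq2 1.42.0 recovered 28% and 64%, with 32.4% of its calls unchanged. No other gene was changed and the spread was the one edgeR estimated, so these shares do not carry over to the data. Overlaps between the comparisons with WT organoids were set beside 10 simulations of all 20 libraries with every group at the WT mean. Those called at most 1 gene in a comparison, so their genes were ranked by p and as many taken as had been called in the data, a step chosen after seeing the data. Camera at the preset correlation called a simulated changed list and did not call an unchanged one. Genes were drawn independently there, so this does not test the preset correlation on lists of correlated genes. Alternatives tried were no filter on low counts, DESeq2, its size factors (RLE) in edgeR, a replicate block, only the libraries compared, each 6 day PyMT set alone, and each library left out in turn. Chosen after seeing the data were a fit without PyMT organoids day 6 replicate 3 and Neu-NT tumor section replicate 3, the 2 libraries that stood apart, and a fit with Neu-NT replicates 1 and 2 summed. No library was left out of the values reported unless said.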

Results

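Polyadenylated RNA was sequenced from 20 mouse mammary samples of the FVB background. Normal mammary organoids (WT organoids), which are fragments of gland grown in a basement membrane gel with the growth factor FGF2, gave 3 libraries after 6 days of culture. MMTV-PyMT mice, whose mammary tumors are driven by the polyoma virus middle T antigen, gave 3 libraries of 30 µm tumor sections, 3 of organoids at day 0 and 3 of organoids at day 6. A further 2 PyMT organoid libraries carry no day in their titles and are described with the same 6 days of culture (undated organoids). MMTV-Neu-NDL mice, which express an activated Neu (ErbB2) receptor, gave 3 libraries of organoids after 6 days. MMTV-Cre;Flox-Neo-Neu-NT mice, in which Cre switches on another activated Neu, gave 3 libraries of tumor sections. The libraries held between 17478357 and 48341438 reads counted on genes. The labels do not say that the replicates came from separate animals, so the p-values measure the spread between these samples.

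The 6 day PyMT organoids, day 6 and undated together, held far fewer smooth muscle transcripts, which mark the myoepithelial layer of the gland, than normal organoids. Of the 17 measured basal and myoepithelial markers 8 fell and none rose over all genes tested, and 9 fell when adjusted over the list alone. The fall was not particular to this list. Median log2 fold changes were -1.41 for basal, -1.37 for fibroblast, -1.69 for endothelial, -1.965 for adipocyte and -2.98 for skeletal muscle and erythroid markers. Those of luminal, macrophage and lymphocyte markers were -0.14, 0.70 and 0.64. Acta2, the smooth muscle actin of myoepithelial cells, stood at 612 ± 118 CPM (scaled counts, mean ± SD, n = 3) in WT organoids. It was at 19.3 ± 5.83 CPM in day 6 organoids (n = 3) and at 30.3 ± 15.7 CPM in undated organoids (n = 2). Its log2 fold change was -4.66 (SE 0.55, adjusted p = 0.000999), and Tagln (-4.40, SE 0.59, adjusted p = 0.00144) and smooth muscle myosin Myh11 (-5.24, SE 0.72, adjusted p = 0.00168) fell with it. The progesterone receptor gene Pgr was at 65.8 ± 15.1 CPM in WT (n = 3), 0.927 ± 0.888 CPM in day 6 (n = 3) and 1.27 ± 1.33 CPM in undated organoids (n = 2). Its log2 fold change over the 6 day groups together was -5.91 (SE 0.83, adjusted p = 0.0017).

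Among the largest falls in the same comparison were Dmbt1, a scavenger receptor gene (log2 fold change -9.52, adjusted p = 0.0116), Reln, which encodes reelin (-6.78, adjusted p = 0.00391), and the amine oxidase gene Aoc1 (-8.07, adjusted p = 0.00211). The interferon-induced Oas2, which encodes an oligoadenylate synthetase, rose from 1.67 ± 1.28 CPM (n = 3, log2 fold change 3.64, SE 0.82, adjusted p = 0.0258). Clca3a2 (4.66, SE 0.74, adjusted p = 0.00381), the adrenergic receptor gene Adrb1 (3.12, SE 0.54, adjusted p = 0.00677) and Gne, a sialic acid synthesis gene (3.10, adjusted p = 0.0158), rose as well. Gabra4, a GABA receptor subunit gene, had 2 counts over the 3 WT libraries and was 810-fold higher in PyMT organoids (95% counting interval 224 to 6690, adjusted p = 0.00144). Intervals and floors here and elsewhere cover counting error only.

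Cell cycle and mitosis genes rose in 3 of 22 over all genes, and 11 rose and 1 fell when adjusted over the list alone. Plk1, a mitotic kinase gene (log2 fold change 1.20, SE 0.30, adjusted p = 0.0369), and Cdc20 (1.11, SE 0.25, adjusted p = 0.024) were among them. The list was higher than other genes (camera adjusted p = 2.13e-08, adjusted p = 0.659 with an estimated correlation). The interferon response list had 3 of 20 genes higher (6 adjusted over the list alone), and antigen presentation 2 of 14 (7 adjusted over the list alone). The interferon list had a camera adjusted p = 0.000186 (adjusted p = 0.659 with an estimated correlation). The antigen presentation list had a camera adjusted p = 0.000219 (adjusted p = 0.659 with an estimated correlation). The basal list was lower (camera adjusted p = 3.19e-09; adjusted p = 0.101 with an estimated correlation). Of 18698 genes tested across the 20 libraries, 262 were higher and 466 lower in 6 day PyMT organoids. The library titled PyMT organoids day 6 replicate 3 stood apart from the other 4 of its kind in markers of other cell types. Its mean log2 CPM was 4.37 for macrophage and myeloid markers (others 0.01 to 1.59) and 3.79 for endothelial markers (others -0.84 to -0.50). It also had the highest antigen presentation mean, 6.44 (others 4.0 to 4.58, WT organoids 3.76 to 4.18). Without it and Neu-NT tumor section replicate 3, the 2 libraries that stood apart, 1390 genes were higher and 1681 lower in this comparison, 726 of the 728 calls were kept, and 16 of 22 cell cycle genes were higher.

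**Figure D1:**
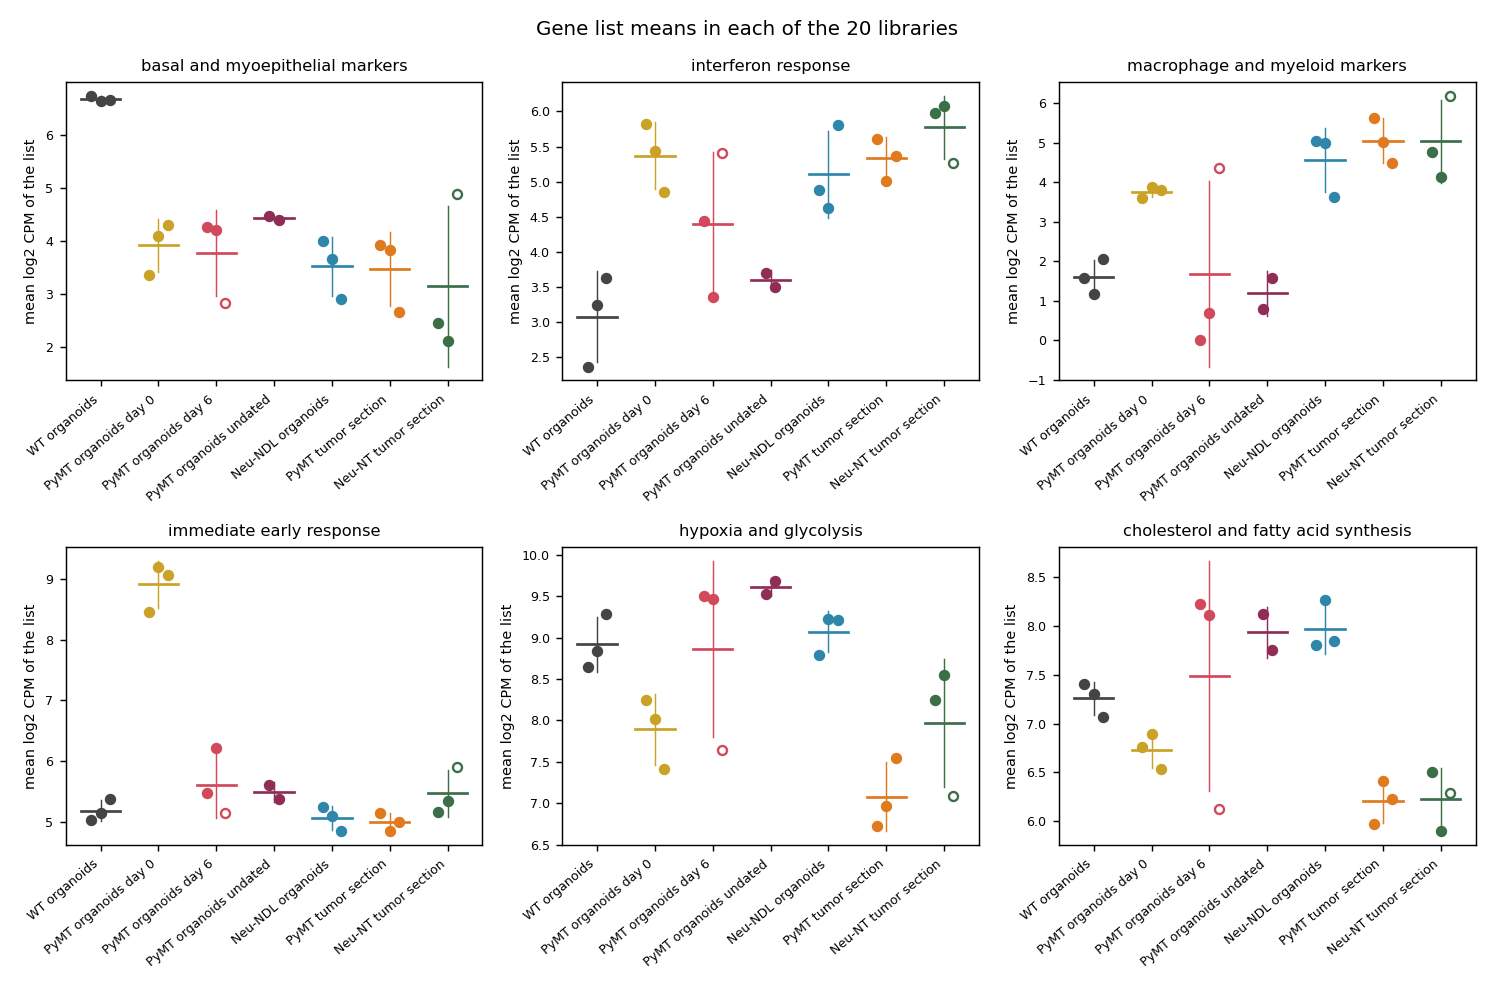
Mean log2 CPM of gene lists in each library by group; points are libraries, horizontal lines group means, vertical lines SD, and open circles the 2 libraries that stood apart. Basal and myoepithelial markers lay between 6.63 and 6.73 in the 3 WT libraries and between 2.10 and 4.89 in all others, and immediate early genes between 8.47 and 9.20 in day 0 organoids and between 4.84 and 6.21 in all others.

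Neu-NDL organoids carried the highest Erbb2 level of the 7 groups. Erbb2 (ENSMUSG00000062312.5, chromosome 11, 98412470 to 98437716, mm10), the mouse Neu gene, was at 6196 ± 2089 CPM in them (n = 3) and at 94.1 ± 3.81 CPM in WT organoids (n = 3). The log2 fold change was 6.04 (SE 0.52, adjusted p = 6.9e-05). Counts on Erbb2 can include reads of a Neu transgene. Spry4, a feedback inhibitor of receptor tyrosine kinase signaling, rose from 17.4 ± 2.42 to 103 ± 5.18 CPM (n = 3 each, log2 fold change 2.57, SE 0.60, adjusted p = 0.026). It was the 1 gene called of 16 MAPK feedback genes, over all genes and adjusted over the list alone (camera adjusted p = 0.0248, adjusted p = 0.444 with an estimated correlation). Basal and myoepithelial markers fell here too, 8 of 17 (10 adjusted over the list alone), including Acta2 (-3.96, SE 0.63, adjusted p = 0.0067) and calponin Cnn1 (-4.49, SE 0.81, adjusted p = 0.00972). The list's call held with an estimated correlation (camera adjusted p = 3.36e-11, adjusted p = 0.0301 with an estimated correlation). So did that of the luminal markers, of which 2 of 20 fell (1 up and 6 down adjusted over the list alone). The luminal list had a camera adjusted p = 0.000585 (adjusted p = 0.0301 with an estimated correlation).

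Macrophage genes were higher in Neu-NDL organoids, 6 of 19 over all genes and 15 adjusted over the list alone. Csf1r, the receptor for macrophage colony stimulating factor, went from 2.96 ± 0.918 to 61.2 ± 25.9 CPM (n = 3 each, log2 fold change 4.37, SE 1.01, adjusted p = 0.0249). The macrophage surface gene Adgre1 (3.92, SE 0.94, adjusted p = 0.0288) and the lysosomal Cd68 (2.83, SE 0.36, adjusted p = 0.00218) rose with it. The list was higher than other genes (camera adjusted p = 8.77e-10, adjusted p = 0.256 with an estimated correlation). Interferon response genes rose in 10 of 20 (18 adjusted over the list alone), including Oas1a (3.36, SE 0.55, adjusted p = 0.0081), Irf7 (2.89, SE 0.69, adjusted p = 0.029) and Stat2 (1.56, SE 0.28, adjusted p = 0.00972). The interferon list had a camera adjusted p = 4.4e-12 (adjusted p = 0.253 with an estimated correlation). Antigen presentation genes rose in 3 of 14 (10 adjusted over the list alone). The antigen presentation list had a camera adjusted p = 6.37e-08 (adjusted p = 0.244 with an estimated correlation). Ribosomal protein genes fell in 10 of 22 (21 adjusted over the list alone). The ribosomal protein list had a camera adjusted p = 1.44e-13 (adjusted p = 0.244 with an estimated correlation).

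The largest falls included Lgr5, which encodes an R-spondin receptor (log2 fold change -5.41, adjusted p = 0.0257), and Wif1, a secreted Wnt inhibitor (-5.56, adjusted p = 0.00944). Pgr (-5.87, adjusted p = 0.0082) and the growth factor pleiotrophin, Ptn, also fell, Ptn from 242 ± 33.5 to 10.1 ± 12.2 CPM (n = 3 each, adjusted p = 0.0092). The largest rises included the mitochondrial carrier gene Slc25a34, from 0.647 ± 0.173 to 142 ± 58.9 CPM (n = 3 each, log2 fold change 7.78, adjusted p = 0.00944). The adenylyl cyclase gene Adcy8 (8.85, adjusted p = 0.0319) and the lysozyme gene Lyz1 (7.20, adjusted p = 0.0206) rose strongly too. Among predicted or noncoding genes, Gm16010 (ENSMUSG00000085541.1, chromosome 9, 97015966 to 97022043), annotated antisense to Spsb4, rose by a log2 fold change of 6.54 (adjusted p = 0.0355). The lincRNA 4833427F10Rik (ENSMUSG00000092171.1, chromosome 17, 35772450 to 35780687) rose by 2.49 (adjusted p = 0.0408). Gas5, a host gene of small nucleolar RNAs, fell from 441 ± 79.1 to 177 ± 76.1 CPM (n = 3 each, adjusted p = 0.0285). It was 1 of 4 named long noncoding RNAs of 31 that fell (2 up and 7 down adjusted over the list alone). The long noncoding list had a camera adjusted p = 0.143. In all, 461 genes were higher and 385 lower. Without the 2 libraries that stood apart, neither of which is in this comparison, the counts were 1562 and 1137, and 844 calls were shared. Leaving out WT replicate 1, 2 or 3 lowered the total to 150, 169 and 115. Strand and annotation release are not given, so reads of antisense or overlapping genes cannot be separated.

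Immune cell markers were higher in PyMT tumor sections than in WT organoids. Macrophage markers were higher in 10 of 19 genes (16 adjusted over the list alone). Csf1r was at 83.4 ± 28.0 CPM (n = 3, log2 fold change 4.82, SE 1.03, adjusted p = 0.0123) and the fractalkine receptor gene Cx3cr1 at a log2 fold change of 6.61 (SE 1.58, adjusted p = 0.0179). The macrophage list had a camera adjusted p = 5.15e-09 (adjusted p = 0.294 with an estimated correlation). T, NK and B cell markers were higher in 8 of 18 (14 adjusted over the list alone). The lymphocyte list had a camera adjusted p = 6.79e-07 (adjusted p = 0.364 with an estimated correlation). Beta globin Hbb-bs, a red blood cell transcript with no count in WT organoids, was at 52.7 ± 16.3 CPM (n = 3), at least 2080-fold higher (3 counts over the group as the floor, adjusted p = 0.0213). Interferon response genes rose in 15 of 20 (19 adjusted over the list alone), including Irf7 (3.80, SE 0.72, adjusted p = 0.0076). Antigen presentation genes rose in 7 of 14 (11 adjusted over the list alone), including the class II gene H2-Ab1 (6.18, SE 1.25, adjusted p = 0.00993). The interferon list had a camera adjusted p = 1.01e-10 (adjusted p = 0.294 with an estimated correlation). The antigen presentation list had a camera adjusted p = 8.1e-08 (adjusted p = 0.236 with an estimated correlation).

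Hypoxia and glycolysis genes were lower in these sections than in the cultured normal organoids, 14 of 22 (17 adjusted over the list alone). The hypoxia and glycolysis list had a camera adjusted p = 2.4e-10 (adjusted p = 0.294 with an estimated correlation). The glycolytic enzyme gene Pgk1 was at 226 ± 74.2 CPM in sections and 1629.9 ± 356 CPM in WT organoids (n = 3 each, log2 fold change -2.85, SE 0.63, adjusted p = 0.0141). The glucose transporter gene Slc2a1 (-1.71, SE 0.38, adjusted p = 0.0144) and Vegfa (-2.62, SE 0.68, adjusted p = 0.0247) fell as well. Cholesterol and fatty acid synthesis genes fell in 9 of 20 and rose in 1 (13 and 1 adjusted over the list alone), for example the isoprenoid enzyme gene Idi1 (-1.95, SE 0.46, adjusted p = 0.0176). The cholesterol list had a camera adjusted p = 9.27e-05 (adjusted p = 0.56 with an estimated correlation). Ribosomal protein genes fell in 16 of 22 (all 22 adjusted over the list alone). The ribosomal protein list had a camera adjusted p = 8.91e-14 (adjusted p = 0.236 with an estimated correlation). Basal markers fell in 8 of 17 (11 adjusted over the list alone), among them P-cadherin Cdh3 (-3.79, SE 0.63, adjusted p = 0.00506). The basal list had a camera adjusted p = 5.15e-09 (adjusted p = 0.141 with an estimated correlation). Luminal markers fell in 5 of 20, in both counts (camera adjusted p = 0.0181; adjusted p = 0.154 with an estimated correlation), including the transcription factor gene Foxa1 (-6.03, SE 1.29, adjusted p = 0.0124).

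Some of the largest rises varied widely between the 3 sections. The secretoglobin Scgb1b27 had no count in WT organoids and 1318, 26.6 and 10372 CPM in PyMT sections 1 to 3, a mean at least 154000-fold higher (adjusted p = 0.0269). Pip, the prolactin-induced protein gene, was at 648 ± 819 CPM (n = 3, adjusted p = 0.0267). The largest falls included Krt6a, a keratin of stratified epithelium, which went from 247 ± 33.8 to 0.409 ± 0.428 CPM (n = 3 each, adjusted p = 0.0289), and Ivl, which encodes involucrin and was at least 576-fold lower (adjusted p = 0.023). The lincRNA Gm21718 (ENSMUSG00000094991.2, chromosome 14, 51311497 to 51317768) was at least 2390-fold higher (adjusted p = 0.0241). The genes Gm15433 (at least 724-fold), Gm16025 (at least 677-fold) and Gm7609 (at least 486-fold) lie near each other on chromosome 1 (84963669 to 85342615). Gm16025 and Gm7609 overlap other annotated genes there, so reads may be assigned wrongly, which was not tested. Erbb2 did not pass the test (log2 fold change 0.03, SE 0.42, adjusted p = 0.969). Over all genes 1206 were higher and 1131 lower (2632 and 2392 without the 2 libraries that stood apart). Tissue, culture and genotype differ together in this comparison and cannot be separated.

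Neu-NT tumor sections had Erbb2 at 711 ± 460 CPM (860, 1077 and 195 CPM in replicates 1 to 3; log2 fold change over WT organoids 2.92, SE 0.45, adjusted p = 0.000871). Its neighbor Grb7, an adaptor that binds ErbB2, rose further, to 2285, 2951 and 436 CPM, against 45.4 ± 10.5 CPM in WT organoids (n = 3, log2 fold change 5.38, SE 0.59, adjusted p = 0.000108). Stard3, which lies between Cdk12 and Erbb2 and was singled out after its values were seen, was at 5403, 5097 and 315 CPM. Across the genes from Med1 to Grb7 (chromosome 11, 98152154 to 98455373), leaving out Erbb2, the median log2 ratio to WT organoids was 5.73, 5.56 and 3.01 in replicates 1 to 3, over the genes with enough counts. Replicate 3 was not raised throughout: its values ran from -0.81 for Cdk12 to 3.47 for Stard3. Over all 8 tested protein coding genes between Med1 and Grb7 its median was 0.88 (95% bootstrap interval 0.27 to 3.03). Those 8 include Neurod2, Ppp1r1b, Tcap and Pnmt, which had too few counts for the first median and lay at 0.93 or below. Of the others, Stard3, Pgap3 and Mien1 lay at 3.47, 2.99 and 3.03, and Cdk12 at -0.81. Replicate 3 alone also had a raised segment from Ormdl3 to Mlx (98581256 to 101092207), with a median of 2.82 over its genes against -0.23 and -0.24 in replicates 1 and 2. In the 3 Neu-NDL libraries the Med1 to Grb7 median was at most 0.13. Of the 16 ErbB receptor and ligand genes, Grb7 among them, 4 rose and 5 fell (4 and 6 adjusted over the list alone). The ErbB list had a camera adjusted p = 0.912.

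**Figure D2:**
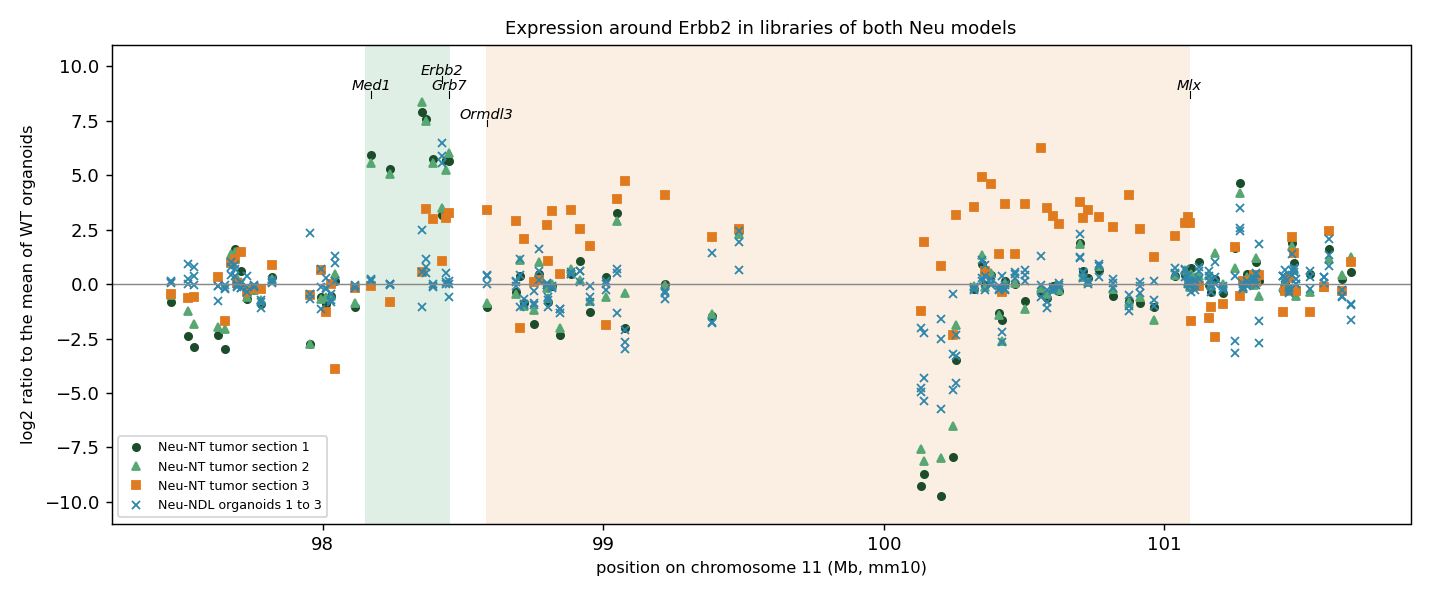
Log2 ratio to the mean of WT organoids for genes along chromosome 11 (position in Mb, mm10); each point is a gene in a library, shading marks the Med1 to Grb7 and the Ormdl3 to Mlx segments. Neu-NT replicates 1 and 2 are high from Med1 to Grb7 (medians 5.73 and 5.56), replicate 3 is high over part of that segment and from Ormdl3 to Mlx (2.82), and Neu-NDL libraries are high at Erbb2 itself.

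Immune and antigen presentation genes were broadly higher in the Neu-NT sections than in WT organoids. As with the PyMT sections, tissue, culture and genotype differ together between Neu-NT sections and WT organoids and cannot be separated. Interferon response genes rose in 18 of 20 (18 adjusted over the list alone), among them Usp18 (log2 fold change 4.37, SE 0.69, adjusted p = 0.00104) and Bst2, which encodes tetherin (3.58, SE 0.42, adjusted p = 0.000168). The interferon list had a camera adjusted p = 8.8e-12 (adjusted p = 0.425 with an estimated correlation). Antigen presentation genes rose in 12 of 14 (all 14 adjusted over the list alone), including B2m, the class I light chain gene (2.93, SE 0.52, adjusted p = 0.00188), and H2-K1 (1.67, SE 0.37, adjusted p = 0.00612). The antigen presentation list had a camera adjusted p = 5.13e-09 (adjusted p = 0.271 with an estimated correlation). Macrophage markers rose in 14 of 19 (15 adjusted over the list alone), including Cd68 (2.44, SE 0.35, adjusted p = 0.00051). The macrophage list had a camera adjusted p = 2.4e-08 (adjusted p = 0.428 with an estimated correlation). T, NK and B cell markers rose in 12 of 18 (15 adjusted over the list alone). The lymphocyte list had a camera adjusted p = 1.15e-06 (adjusted p = 0.44 with an estimated correlation). Replicate 3 stood apart from replicates 1 and 2 in these lists, with a mean log2 CPM of 1.84 for T, NK and B cell markers against -1.06 and -0.62. Beyond these lists its counts were closest to those of PyMT tumor section 2, at a chi-square per gene of 290. To Neu-NT replicates 2 and 1 it was 402 and 433. This measure grows with depth, and section 2 held the fewest counts. By Spearman correlation replicate 3 was closest to PyMT tumor section 1 (0.933), with 0.931 for section 2. For Neu-NT replicates 2 and 1 the values were 0.914 and 0.917.

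Milk genes rose in 9 of 16 (11 adjusted over the list alone), though not beyond other genes (camera adjusted p = 0.0966). Csn2, beta casein, was at 18.8, 296 and 24215 CPM in replicates 1 to 3 against 0.0604 ± 0.0597 CPM in WT organoids (n = 3, log2 fold change 16.97, adjusted p = 0.00148). Without the 2 libraries that stood apart its log2 fold change was 11.29. Csn3, kappa casein, rose by a log2 fold change of 3.34 (SE 0.87, adjusted p = 0.0156). Without those 2 libraries 5 milk genes were higher and 3 lower. Of 16 imprinted genes 8 fell and 1 rose (9 and 1 adjusted over the list alone), for example Mest (-4.83, SE 1.04, adjusted p = 0.00573). The imprinted list had a camera adjusted p = 0.0012 (adjusted p = 0.428 with an estimated correlation). Cholesterol and fatty acid synthesis genes fell in 6 of 20 (10 down and 1 up adjusted over the list alone), with Elovl6, a fatty acid elongase gene, at -2.56 (SE 0.50, adjusted p = 0.00357). The cholesterol list had a camera adjusted p = 0.000564 (adjusted p = 0.638 with an estimated correlation). Heat shock and unfolded protein response genes rose in 5 of 18 (5 adjusted over the list alone), among them the chaperone gene Hspa5 (1.51, SE 0.27, adjusted p = 0.00227). The heat shock list had a camera adjusted p = 0.00488 (adjusted p = 0.522 with an estimated correlation).

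Hypoxia and glycolysis genes fell in 4 of 22 (6 adjusted over the list alone) and ribosomal protein genes in 8 of 22 (15 adjusted over the list alone). The hypoxia and glycolysis list had a camera adjusted p = 0.00119 (adjusted p = 0.731 with an estimated correlation). The ribosomal protein list had a camera adjusted p = 1.78e-06 (adjusted p = 0.513 with an estimated correlation). Basal markers fell in 9 of 17 (9 down and 1 up adjusted over the list alone), including basal keratin Krt5 (-6.61, SE 1.94, adjusted p = 0.0266). The basal list had a camera adjusted p = 1.78e-06 (adjusted p = 0.271 with an estimated correlation). Pgr (-9.45, adjusted p = 0.000266) and the desmosomal cadherin gene Dsc3 (-9.29, adjusted p = 0.00477) were among the largest falls. Single sections carried some of the largest rises. Ikzf3, a lymphoid transcription factor gene next to Grb7, was at 102 CPM in replicate 2 and at 2.57 and 2.54 CPM in replicates 1 and 3. The matrilysin gene Mmp7 was at 45.2 CPM in replicate 3 and no longer passed the test without the 2 libraries that stood apart (log2 fold change 6.08, adjusted p = 0.107). The lincRNA Gm14133 (ENSMUSG00000087029.1, chromosome 2, 149743927 to 149798743), with 1 count in WT organoids, was 3300-fold higher (95% counting interval 591 to 130000, adjusted p = 0.00676), and Gm16010 rose by a log2 fold change of 7.66 (adjusted p = 0.00753). In all 1972 genes were higher and 1583 lower (2728 and 2656 without those 2 libraries, which leaves Neu-NT replicates 1 and 2). With these summed to 1 library beside replicate 3, 1516 were higher and 942 lower.

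A question the series poses is which transcripts, long noncoding ones included, are raised in mammary tumors of several models. Over the 4 comparisons with WT organoids, 40 genes were higher in every one. The number ran from 4 to 74 when 1 library was left out, and was 130 without the 2 libraries that stood apart, 39 of the 40 among them. Lists drawn independently would share 0.0439 genes. In 10 simulations with no true change and the same WT libraries in every comparison, lists of the same sizes, taken by rank, shared 46 to 74 genes. Those ranked lists are not calls, since the simulations called at most 1 gene in a comparison. They show that shared WT libraries can raise an overlap of ranked lists. They cannot decide how many of the 40 come from the shared WT libraries. Oas2 rose by a log2 fold change of at least 3.64 in each comparison, and 3 of the 20 interferon response genes, Oas1a, Bst2 and Gbp2, were among the 40. Clca3a2, Adrb1 and Gne rose in all 4. A single gene annotated as long noncoding did so: Zfp469 (ENSMUSG00000043903.3, annotated as a lincRNA, chromosome 8, 122269569 to 122272650), overlapped on the same strand by the protein coding model Gm20388. The annotation is the only evidence here that Zfp469 is noncoding. Its reads may come from a protein coding transcript, which was not tested. Its log2 fold change was 2.50 (SE 0.47, adjusted p = 0.0103) in 6 day PyMT organoids, 2.36 (SE 0.49, adjusted p = 0.0173) in Neu-NDL organoids, 2.18 (SE 0.49, adjusted p = 0.0141) in PyMT sections and 2.62 (SE 0.49, adjusted p = 0.0027) in Neu-NT sections. Its level was 1.45 ± 0.434 CPM in WT organoids (n = 3). Independent lists would share 0.000447 such genes, and the simulated ones shared 1 to 5. No long noncoding gene was left in all 4 when any 1 WT library, undated replicate 1 or Neu-NDL replicate 2 was left out. There were 5 without the 2 libraries that stood apart and 10 by DESeq2.

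In the other direction 88 genes were lower in all 4 comparisons, against 0.0491 for independent lists and 22 to 33 in the simulations. They included Pgr, which fell by at least 4.64 on the log2 scale in each, Ptn (smallest fall -4.57), and the contractile genes Acta2 (smallest fall -3.21) and Myh11 (smallest fall -3.28). Because all 4 comparisons use the same 3 WT libraries, and these come from culture, the overlaps include whatever is particular to those libraries, and no excess here is read as a shared effect. Among long noncoding genes, 9 were higher and 58 lower in 6 day PyMT organoids, 25 and 23 in Neu-NDL organoids, 94 and 100 in PyMT sections, and 161 and 109 in Neu-NT sections, of 1967 tested. These counts, without the 2 libraries that stood apart, were 47 and 239, 102 and 57, 221 and 180, and 266 and 143. Zfas1, a small nucleolar RNA host gene, fell in each of the 4, with log2 fold changes of -1.10 (adjusted p = 0.0244), -1.44 (adjusted p = 0.0146), -1.26 (adjusted p = 0.0143) and -1.16 (adjusted p = 0.0108).

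**Figure D3:**
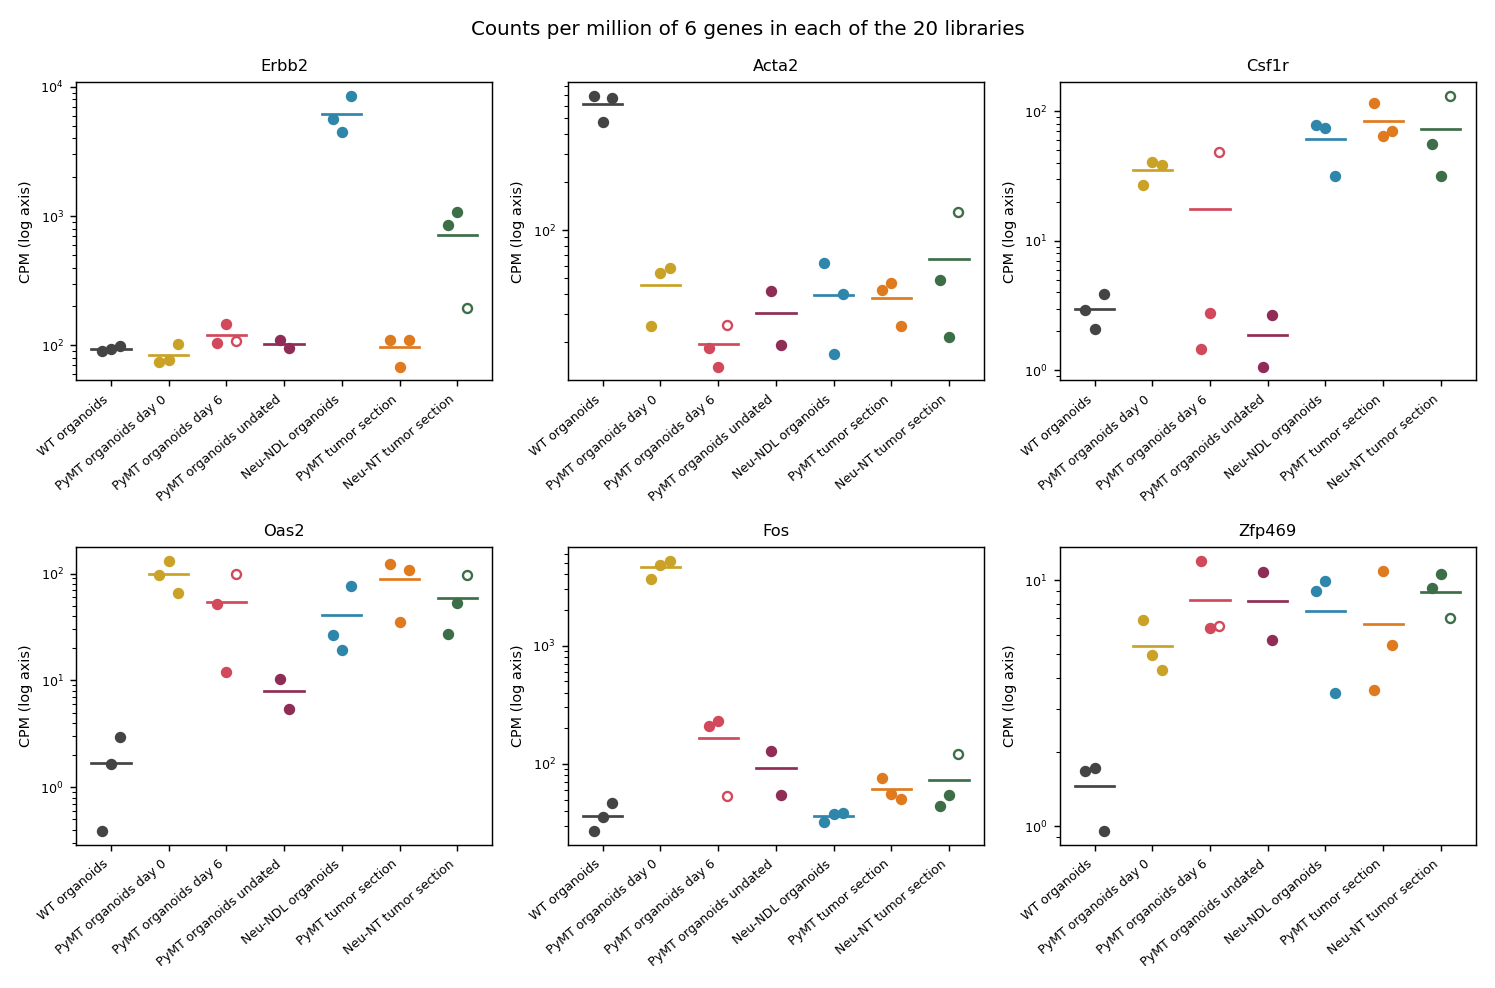
Scaled counts (CPM, log axis) of 6 genes in each of the 20 libraries by group; points are libraries, horizontal lines group means, and open circles the 2 libraries that stood apart. Erbb2 averaged 6196 CPM in Neu-NDL organoids and 711 CPM in Neu-NT sections against 94.1 CPM in WT organoids, Acta2 was highest in the WT organoids, and Fos in the day 0 organoids.

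Immediate early genes were high in PyMT organoids at day 0 and low after 6 days of culture. Of 20 such genes 12 fell between day 0 and day 6 (16 adjusted over the list alone), and the call held with an estimated correlation (camera adjusted p = 4.18e-36, adjusted p = 0.000872 with an estimated correlation). Fosb, an AP-1 transcription factor gene, went from 2321.5 ± 654 to 8.82 ± 1.21 CPM (n = 3 each, log2 fold change -8.04, SE 0.50, adjusted p = 5.95e-07). Fos went from 4583 ± 805 to 165 ± 97.7 CPM (n = 3 each, -4.79, SE 0.55, adjusted p = 0.000377). Jun (-4.10, SE 0.35, adjusted p = 2.07e-05), Egr1 (-4.20, SE 0.54, adjusted p = 0.000853), the stress factor gene Atf3 (-5.24, adjusted p = 0.00722) and the mRNA decay factor gene Zfp36 (-4.39, adjusted p = 7.73e-06) fell in parallel. The inducible heat shock genes Hspa1a (-4.94, adjusted p = 0.000538) and Hspa1b (-4.19, SE 0.54, adjusted p = 0.00086) were among 3 of 18 heat shock and unfolded protein response genes that fell (8 down and 1 up adjusted over the list alone). The heat shock list had a camera adjusted p = 2.54e-06 (adjusted p = 0.489 with an estimated correlation). The neutrophil chemokine gene Cxcl2 also fell (-5.18, adjusted p = 0.00664).

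Genes that rose by day 6 included Fgfbp1, which encodes a carrier that releases FGFs from the matrix (log2 fold change 5.99, SE 1.15, adjusted p = 0.0251), Dram1, an autophagy gene (2.86, adjusted p = 0.0339), and the phospholipase gene Pla2g7 (2.77, adjusted p = 0.0143). Cell cycle genes had no member called over all genes and 12 of 22 higher adjusted over the list alone (camera adjusted p = 9.02e-11, adjusted p = 0.492 with an estimated correlation). Hypoxia and glycolysis genes had none and 15 of 22 (camera adjusted p = 1.9e-09, adjusted p = 0.492 with an estimated correlation). Over all genes 31 were higher and 86 lower. The higher calls were the less stable: 0 were left, with 4 lower, in a fit of only the libraries compared, and 0, with 49 lower, without day 0 replicate 2. Day 0 and day 6 libraries of the same number resembled each other, so they were also compared within pairs, which gave 15 higher and 78 lower. With pairing 12 of 20 immediate early genes fell (16 adjusted over the list alone), while caveolin Cav1 (2.48, adjusted p = 0.0905 paired; adjusted p = 0.0486 unpaired) no longer passed. Without the 2 libraries that stood apart, which leaves 2 day 6 libraries, 1759 genes were higher and 1740 lower, the endothelial list had 14 of 15 markers lower and the macrophage list 15 of 19 lower and 1 higher.

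Immediate early genes also set the day 0 organoids apart from the PyMT tumor sections. Of 20 such genes 16 were higher at day 0 (19 adjusted over the list alone), and the list test held. The immediate early list had a camera adjusted p = 4.97e-73 (adjusted p = 2.04e-05 with an estimated correlation). They included Fosb (log2 fold change 8.26, SE 0.51, adjusted p = 4.53e-07), Fos (6.23, SE 0.59, adjusted p = 3.38e-05), Jun (4.40, SE 0.36, adjusted p = 9.34e-06) and the matricellular Ccn1 (4.56, adjusted p = 0.00023). Of 22 chemokine and inflammation genes 4 were higher (6 adjusted over the list alone), with Tnf (4.31, SE 0.70, adjusted p = 0.00568) and Cxcl2 (5.76, adjusted p = 0.00263) as examples. The chemokine list had a camera adjusted p = 7.33e-09 (adjusted p = 0.0556 with an estimated correlation). The EGF receptor ligand gene Hbegf (4.27, SE 0.61, adjusted p = 0.00157) and Socs3, a feedback inhibitor of cytokine signaling (4.62, adjusted p = 0.000836), were higher too. Heat shock genes rose in 3 of 18 (8 adjusted over the list alone), including Hspa1b (3.94, SE 0.54, adjusted p = 0.00103). The heat shock list had a camera adjusted p = 3e-11 (adjusted p = 0.0556 with an estimated correlation). No macrophage or fibroblast gene was called, though both lists were lower at day 0 than other genes (camera adjusted p = 3.3e-06 and 1.3e-06, adjusted p = 0.353 and 0.359 with an estimated correlation).

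Over all genes 80 were higher at day 0 and 3 lower. The 3 were the zinc finger genes Zfp719 (log2 fold change -1.23, adjusted p = 0.0476) and Zfp260 (-0.75, adjusted p = 0.0296) and 2310034G01Rik (-2.76, adjusted p = 0.0225), the last named after its value was seen. With the replicate number as a block Zfp719 (adjusted p = 0.08) and Zfp260 (adjusted p = 0.0612) missed the test and 1 lower gene was left. None was left without section 1, section 2, day 0 replicate 2 or day 0 replicate 3. DESeq2 called 215 genes and the fit without the 2 libraries that stood apart 243, 170 higher and 73 lower.

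PyMT and Neu-NT tumor sections differed in Erbb2 and in genes next to it. Erbb2 was lower in PyMT sections, at 96.3 ± 24.1 CPM (n = 3, log2 fold change -2.88, SE 0.45, adjusted p = 0.00195). In a fit of only the libraries compared it was at -2.90 and missed the test (adjusted p = 0.0703). Grb7 was lower too (-5.31, SE 0.59, adjusted p = 0.000354). Of 16 ErbB receptor and ligand genes 4 were higher and 4 lower (5 and 5 adjusted over the list alone), with Egfr higher (1.69, SE 0.37, adjusted p = 0.0124) and the ligand Hbegf lower (-3.40, SE 0.58, adjusted p = 0.0035) in PyMT. The ErbB list had a camera adjusted p = 0.748. MAPK feedback genes were lower in 3 of 16 (5 adjusted over the list alone), including the ERK phosphatase gene Dusp6 (-1.67, SE 0.40, adjusted p = 0.0188) and the ETS factor gene Etv4 (-2.45, SE 0.53, adjusted p = 0.0113). The MAPK feedback list had a camera adjusted p = 0.018 (adjusted p = 0.801 with an estimated correlation). The immediate early list had 6 lower, among them Junb (-2.13, SE 0.44, adjusted p = 0.00895), and 1 higher (7 and 2 adjusted over the list alone). The immediate early list had a camera adjusted p = 0.153. Neuropeptide Y, Npy, with 2 counts in Neu-NT sections, was 998-fold higher in PyMT sections (95% counting interval 276 to 8250, adjusted p = 0.0109), and Gabra4 was 656-fold higher (224 to 3180, adjusted p = 0.000564).

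Higher in Neu-NT sections were Itih2, which encodes a heavy chain of inter-alpha-trypsin inhibitor (log2 fold change -6.54, adjusted p = 0.00195, 22.9 ± 23.2 against 0.243 ± 0.00721 CPM, n = 3 each), and the kininogen gene Kng2 (-6.96, adjusted p = 0.00561). The largest fitted difference, Glycam1 (-11.77, adjusted p = 0.0159), came from replicate 3 of the Neu-NT sections, at 4046 CPM against 1.63 and 1.71 CPM in replicates 1 and 2. Without the 2 libraries that stood apart it was -2.10 (adjusted p = 0.122). Milk genes turned with those libraries, from 4 of 16 lower in PyMT (5 adjusted over the list alone) to 4 higher and 1 lower. The milk list had a camera adjusted p = 0.801. Over all genes 855 were higher and 959 lower in PyMT sections (2166 and 2151 without the 2 libraries). With Neu-NT replicates 1 and 2 summed to 1 library 811 genes were called, and 771 and 853 without replicate 1 or replicate 2.

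Among 6 day organoids the PyMT and Neu-NDL models differed in Erbb2 (log2 fold change -5.81, SE 0.44, adjusted p = 8.78e-06) and, among other genes, in macrophage markers. These were lower in PyMT organoids in 8 of 19 (14 down and 1 up adjusted over the list alone). The macrophage list had a camera adjusted p = 1.1e-08 (adjusted p = 0.861 with an estimated correlation). Csf1r (-3.42, SE 0.82, adjusted p = 0.0244), Adgre1 (-4.06, SE 0.80, adjusted p = 0.0121) and the integrin gene Itgam (-4.28, SE 0.74, adjusted p = 0.00818) were among them. Gpnmb, a lysosomal glycoprotein gene, was at 121 ± 90.2 CPM in Neu-NDL (n = 3), 0.590 ± 0.310 CPM in day 6 (n = 3) and 1.93 ± 0.0289 CPM in undated PyMT organoids (n = 2). Its log2 fold change over the 6 day PyMT groups together was -6.80 (SE 0.97, adjusted p = 0.00304). Higher in PyMT were the axon guidance gene Slit1 (6.43, adjusted p = 0.00934), the VEGF receptor gene Flt1 (3.76, SE 0.56, adjusted p = 0.00359), the tetraspanin gene Tspan18 (3.55, adjusted p = 0.00304) and keratin Krt7 (2.37, SE 0.45, adjusted p = 0.0104). Erbb4 was lower (-3.89, SE 0.80, adjusted p = 0.0141).

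Cell cycle genes were higher in PyMT in 2 of 22 (4 up and 1 down adjusted over the list alone) and ribosomal protein genes in 4 of 22 (6 adjusted over the list alone). The cell cycle list had a camera adjusted p = 4.23e-05 (adjusted p = 0.89 with an estimated correlation). The ribosomal protein list had a camera adjusted p = 2.25e-07 (adjusted p = 0.89 with an estimated correlation). Interferon response genes were lower in 2 of 20 (6 adjusted over the list alone). The interferon list had a camera adjusted p = 4.23e-05 (adjusted p = 0.89 with an estimated correlation). Over all genes 453 were higher and 878 lower. Taken as 1 group of 5 PyMT libraries against 3, the comparison called 893 genes, and 5 of the 56 splits of these libraries, the real one included, called at least as many. Day 6 replicate 3, whose macrophage mean lay near those of the Neu-NDL libraries (4.37 against 3.62 to 5.04), sits on the PyMT side. Without the 2 libraries that stood apart 2003 genes were higher and 2511 lower, 16 of 19 macrophage markers were lower and 1 higher, and 11 of 22 cell cycle genes were higher.

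The undated and day 6 PyMT organoids, which share their described culture time, had 0 genes called by edgeR, with 2423 at an unadjusted p under 0.05, and 398 called by DESeq2. No member of any list was called over all genes. Adjusted over the list alone, 9 of 22 ribosomal protein genes and 4 of 15 mitochondrially encoded genes were higher in the undated set, and 5 of 15 endothelial markers were lower (camera adjusted p = 1.69e-05, 2.48e-05 and 0.0459, adjusted p = 0.726 with an estimated correlation for each). Single libraries lay apart in each of these lists. The ribosomal mean was 10.67 in undated replicate 2 (9.94 to 10.06 in the other 4), the mitochondrial mean 7.92 in undated replicate 1 (others 5.82 to 6.32), and the endothelial mean 3.79 in day 6 replicate 3. Erbb2 stood at 102 ± 10.2 CPM (n = 2) and 119 ± 23.4 CPM (n = 3), with a log2 fold change of -0.22 (SE 0.47, adjusted p = 0.866). Leaving out any 1 library of either set gave 0 to 2 calls.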

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

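The mixture test and the counts of splits were written before their results were seen, and the tests of all other explanations in this part were chosen after.

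The library titled PyMT organoids day 6 replicate 3 lay far from the other 4 libraries of 6 day PyMT organoids in 7 of 27 gene lists, where chance puts about 1 in 20 groups past the limit used (Dixon's test, 5 samples). Its mean log2 CPM was 2.83 for basal and myoepithelial markers (others 4.20 to 4.46), 3.79 for endothelial markers (others -0.84 to -0.50), -0.68 for T, NK and B cell markers (others -3.20 to -3.04), 7.49 for heat shock and unfolded protein response (others 6.98 to 7.07), 7.64 for hypoxia and glycolysis (others 9.46 to 9.69), 6.13 for cholesterol and fatty acid synthesis (others 7.75 to 8.22) and 6.44 for antigen presentation (others 4.0 to 4.58). In 2 more lists an undated library lay apart: replicate 1 had a mean of 7.92 for mitochondrially encoded genes (others 5.82 to 6.32), and replicate 2 a mean of 10.67 for ribosomal proteins (others 9.94 to 10.06).

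For day 6 replicate 3, a mixture of 6 day organoid RNA with tumor RNA is argued against, since 39 genes high in the other 4 libraries and low in the sections kept a median of 0.0239% of their level (95% bootstrap interval -0.0221 to 0.464%), against 54.6 to 206% in single libraries of the other 4. A day 0 organoid library under this title is argued against by Fos at 53.2 CPM, far below the day 0 libraries. A tumor tissue library under this title stays open as a candidate explanation: its closest library was PyMT tumor section replicate 3, at a chi-square per gene of 37.7, the lowest of the 190 pairs of libraries, in a test that could have named an organoid library. An organoid culture that kept its tumor's other cell types was not tested as a separate explanation. The same 39 genes argue against a culture that only added such cells to the expression seen in the other 4 libraries. The label was left as given.

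Genes next to Erbb2 were high in the Neu-NT tumor sections. In replicates 1 and 2 a gain of the chromosome 11 segment from Med1 to Grb7 may be the cause: the lowest log2 ratio to WT organoids of the 8 tested protein coding genes between them, Erbb2 left out, was 2.67. In replicate 3 the values do not decide on a gain of this segment as a whole, whose edges follow replicates 1 and 2. The median of the same genes was 0.88 (95% bootstrap interval 0.27 to 3.03), with 3 of the 8 above 1, from -0.81 for Cdk12 to 3.47 for Stard3. Neurod2, Ppp1r1b, Tcap and Pnmt, at 0.93 or below, had few counts and weigh on this median. Replicate 3 was also high from Ormdl3 to Mlx, a stretch picked after its values were seen. The median there was 2.82, and the highest of 8854 other runs of 43 neighboring genes had 0.55. A gain with other edges in replicate 3 stays open and was not tested. DNA copy number was not measured. Replicates 1 and 2 may also come from 1 tumor, since their chromosome medians correlated over the 20 chromosomes (r = 0.996) where those with replicate 3 did not (r = 0.203 and 0.169). Chromosomes are not independent replicates, and separate tumors with the same changes stay open.

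Immediate early genes were high in the day 0 organoids. Loss of stromal cells that enriches epithelial RNA is argued against as the source, since luminal markers had a median log2 fold change of only 0.22 against sections. A stress response to the preparation cannot be told apart from other differences: heat shock and unfolded protein response genes had a median of 0.59, and preparation coincides with the group in every library.

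Genes were called between the models in 2 pairs of groups, where the comparison between the models is itself the test of the difference. Between PyMT and Neu-NT tumor sections there were 1814, with a log2 fold change of -2.88 for Erbb2. Between 6 day PyMT and Neu-NDL organoids there were 1331, with -5.81 for Erbb2. Chance is not excluded for the 1331, and with only the libraries compared 11 were called.

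Other splits of the same libraries were refitted for each count. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split was 1 of the 10 in each of 6 comparisons. The real counts and the highest of the other splits were 846 and 0 for Neu-NDL against WT organoids, 2337 and 0 for PyMT sections against WT, 3555 and 0 for Neu-NT sections against WT, 83 and 0 for day 0 organoids against PyMT sections, 1814 and 10 for the sections of both models, and 117 and 27 for day 6 against day 0. In the last, libraries of the same number resembled each other, though no label pairs them. The 3 other splits that part all 3 such pairs gave at most 0, and the 6 that part 1 pair gave up to 27. For the 6 day PyMT organoids taken as 1 group of 5, the real split against WT called 732 genes. Only the real one, 1 of 56 splits, was as large, and the highest other gave 436. That share is under 0.05 without adjustment over the comparisons. It counts against chance only if the libraries are independent samples, which the labels do not say. Against Neu-NDL the real split called 893 genes, 5 of 56 splits were as large, and chance cannot be excluded. The highest other there gave 1550. In all 4 other splits that called as many, day 6 replicate 3 was on the side of at least 2 of the 3 Neu-NDL libraries.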

How the results depend on the processing

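The fit without the 2 libraries that stood apart and the one with Neu-NT replicates 1 and 2 summed were chosen after seeing the data. Of 2942 values of named genes under alternatives, 2301 kept the call or lack of one, 637 lost the call, and 4 reversed. Named genes other than Erbb2 were picked for large, separated differences, so their kept direction is no test. All 4 reversals were of Erbb2 in PyMT sections against WT organoids, which had passed no test: -0.02 without the filter, and -0.085 to 0.217 over the libraries left out in turn. RLE scaling kept every total within 1.5 times, though the higher genes of day 6 against day 0 went from 31 to 20. Of the named genes, 57, 65 and 71 of 138 lost the call without WT 1, 2 and 3, 33 of 53 without undated 1, and 30 of 52 with the undated set alone. Without the filter 58 of 220 lost it, with only the libraries compared 59 of 217, and without the 2 libraries that stood apart 3 of 220. With DESeq2 0 of 208 did, and named values to which it gave no adjusted p were not counted. The cause was not tested for the changes below, except that some settings hold fewer samples by construction. In the single model a library outside a comparison can move its count only through the shared gene filter, scaling and spread. Without PyMT organoids day 6 replicate 3 the count for Neu-NDL against WT organoids, which does not contain it, went from 846 to 1691. Which shared part did so was not tested. Depth limits what could be seen in genes with few counts: 3 counts over the WT libraries correspond to 0.0254 CPM.

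DESeq2 called 1779 genes for 6 day PyMT against WT organoids (48.3% of them higher, 36.0% by edgeR), 2075 for Neu-NDL against WT, 3669 for PyMT sections against WT, 826 for day 6 against day 0, 215 for day 0 against PyMT sections, 3021 between sections, 2620 between 6 day organoids of both models and 398 between undated and day 6, with 163 genes higher in all 4 comparisons, 10 of them long noncoding. In the simulated data, with 100 genes changed 2-fold and 100 changed 4-fold, 44 of its 136 calls were unchanged genes (32.4%). That share depends on how many genes change and does not carry over to the counts here. With only the libraries compared, the counts were 1907 for Neu-NDL against WT, 4870 for PyMT sections against WT, 4 for day 6 against day 0, 191 for day 0 against PyMT sections, 327 between sections and 11 between 6 day organoids. Without the filter they were 834 between 6 day organoids, 1 between undated and day 6, and 19 higher in all 4.

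Without the 2 libraries that stood apart the counts were 3071 for 6 day PyMT against WT, 2699 for Neu-NDL against WT, 5024 for PyMT sections against WT, 5384 for Neu-NT sections against WT, 3499 for day 6 against day 0, 243 for day 0 against sections, 4317 between sections and 4514 between 6 day organoids, with 130 genes higher in all 4 and 5 long noncoding. With Neu-NT replicates 1 and 2 summed, 811 genes differed between sections. The undated set alone gave 88 genes against WT and 645 against Neu-NDL, and the day 6 set alone 131 against Neu-NDL. With the replicate number as a block, which pairs libraries, undated against day 6 gave 2 genes and 12 of 220 named genes lost the call.

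Leaving out 1 library at a time moved the counts widely. For 6 day PyMT against WT they ran from 81 (without undated 1) to 2025 (day 6 replicate 3), with 219, 191 and 176 without WT 1, 2 and 3. For Neu-NDL against WT they ran from 115 (WT 3) to 1691 (day 6 replicate 3), with 150 and 169 without WT 1 and 2, and 1291, 182 and 183 without Neu-NDL 1, 2 and 3. For PyMT sections against WT they ran from 525 (WT 3) to 3949 (day 6 replicate 3), with 761 and 692 without WT 1 and 2, and 561 and 890 without sections 1 and 3. For Neu-NT sections against WT they ran from 1830 (WT 2) to 4674 (day 6 replicate 3), with 2183, 1962 and 2242 without WT 1, WT 3 and Neu-NT 1. For day 6 against day 0 they ran from 41 (day 6 replicate 1) to 2437 (day 6 replicate 3), with 60 without day 6 replicate 2, and 65, 49 and 52 without day 0 replicates 1, 2 and 3. For day 0 against sections they ran from 47 (section 1) to 169 (day 6 replicate 3), with 48 without section 2.

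Between sections the counts ran from 721 (PyMT 1) to 3095 (Neu-NT 3), with 1205 and 862 without PyMT 2 and 3, 771 and 853 without Neu-NT 1 and 2, and 2765 without day 6 replicate 3. Between 6 day organoids they ran from 173 (undated 1) to 3109 (day 6 replicate 3), with 277 without undated 2, and 566 and 577 without Neu-NDL 2 and 3. Between undated and day 6 they ran from 0 to 2 (undated 2), with 1 without day 6 replicate 1. Genes higher in all 4 ran from 4 (WT 1) to 74 (day 6 replicate 2), with 5 and 7 without WT 2 and 3, 8 without undated 1, 16 and 24 without Neu-NDL 2 and 3, 71 without day 6 replicate 3 and 72 without Neu-NT 3. Long noncoding ones ran from 0 (WT 1, 2 or 3, undated 1, Neu-NDL 2) to 3 (day 6 replicate 3, Neu-NT 3), with 2 without day 6 replicate 2 or Neu-NDL 1.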

Other observations

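Neu-NT tumor sections 1 and 2 shared a chromosome pattern that section 3 lacked. Their median log2 ratio to WT organoids was 0.55 and 0.52 on chromosome 2, -0.93 and -0.97 on chromosome 4, and 0.44 and 0.47 on chromosome 12. PyMT tumor section 3 and the library titled day 6 replicate 3 resembled each other, with 0.41 and 0.47 on chromosome 7, 0.50 and 0.55 on chromosome 11, and 0.42 and 0.47 on chromosome 15. Their medians over the 20 chromosomes correlated at r = 0.987, and day 0 replicate 3 correlated with them at 0.925 and 0.924. High correlation was not particular to replicate 3. Undated replicate 2 correlated with them at 0.888 and 0.863 and PyMT tumor section 1 at 0.809 and 0.794. By mean absolute difference of the medians, section 3 and the library titled day 6 replicate 3 were closer, at 0.038. Undated replicate 2 differed from them by 0.143 and 0.156, section 1 by 0.057 and 0.081, and day 0 replicate 3 by 0.068 and 0.093. All ratios share the WT mean. WT replicates 1, 2 and 3 correlated with them at 0.564 and 0.624, -0.658 and -0.687, and 0.631 and 0.630. Chromosomes are not independent replicates.

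The secretoglobin Scgb1b27 followed replicate 3 across the PyMT preparations: it was at 10372 CPM in tumor section 3, 3863 CPM in day 0 organoids 3 and 16646 CPM in the library titled day 6 replicate 3, against at most 1318 CPM in the other PyMT libraries. It was chosen as an example after its values were seen. The lincRNA Gm13387 (ENSMUSG00000087028.4, chromosome 2, 25122603 to 25145396) was at 37.9 ± 39.4 CPM in Neu-NDL organoids (n = 3) and 60.2 ± 52.0 CPM in Neu-NT sections (n = 3), against 0.960 ± 0.143 CPM in WT organoids (n = 3) and 0.459 ± 0.211 CPM in PyMT sections (n = 3). Its rise in Neu-NDL organoids passed the test (log2 fold change 5.30, SE 1.36, adjusted p = 0.0368) and missed it with the replicate number as a block (adjusted p = 0.0515).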
